A study of Litchi chinensis with 12 samples.

How the data were processed

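Small RNA libraries were made from leaves and fruits of lychee (Litchi chinensis, cultivar Feizixiao) collected 24 h after inoculation with spores of Peronophythora litchii at 10000 spores per ml, or after a mock treatment with sterile water. P. litchii is the oomycete that causes lychee downy blight. There were 12 samples in 4 groups of 3, and group, tissue and replicate number were taken from the sample labels. Nothing in the labels says that the samples of a group came from separate plants, so p-values measure the spread between these samples, which may be technical.

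The deposited values were a single table of CPM (reads scaled to a fixed library total) per miRNA entry and library. The table was named as FPKM by the authors, but the values of each library summed to 1000000 without any length term, so they were treated as CPM. Per the submitters' processing notes, the tools used upstream included Bowtie2 2.2.3, TopHat2 2.0.12, HTSeq 0.6.1 and DESeq 1.18.0, with no role stated for any of them. The genome build, the miRBase release and the way reads were assigned to entries were not given in the sources used here. Extraction and library preparation followed a plant RNA kit and an Illumina small RNA kit, per the labels' protocols. No sequence, coordinate or genome was used here, so entries are given by the names in the deposited table.

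Within each library every value was a whole multiple of the smallest value above 0. Taking that smallest value as 1 read gave whole numbers for 100% of values within 0.01 read, and the recovered totals ranged from 282775 to 1521425 reads per library. A read was therefore worth between 0.657 and 3.54 CPM, and the floor that a count of 0 allows (3 reads) was between 1.97 and 10.6 CPM in a single library. Over the 3 mock libraries together that floor was 1.35 CPM in leaf and 2.74 CPM in fruit. Reads carried no molecular identifiers, so intervals and floors cover counting error only.

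The table held 524 entries. Of these, 131 carried the name of a miRNA from another plant species and 393 were numbered novel_miR. Many entries had identical values in every library, as when 1 mature sequence is listed under several species names, and the 524 entries reduced to 394 distinct profiles (52 of named and 342 of novel_miR entries). The largest identical set held 14 entries. Reads of such a sequence were counted once per entry, and distinct profiles held between 51.9% and 65.7% of the recovered reads. Sums over a family therefore count some reads more than once, and entries that differ by few bases can share reads, so the split between members of a family is uncertain.

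Values were tested as log2(CPM + 1) with limma 3.58.1 in R 4.3.3, with a mean-variance trend and all 4 groups in 1 fit with 8 residual degrees of freedom. Entries with at least 1 CPM in at least 3 samples were kept (517 entries, of which 124 were named and 391 were distinct). A fold change is on this log2(CPM + 1) scale and understates the change of low entries. The tests were two-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. The comparisons were inoculated against mock leaf, inoculated against mock fruit, the difference between these 2 effects, and mock fruit against mock leaf. The same test was run on values summed over each of 14 miRNA families, read from the entry names. For the last 2 comparisons the family test was added after the table was seen. Before the data were examined, 8 lists of miRNA families (40 families) were fixed by known target class. Lists with at least 3 tested entries (5 lists) were tested with camera at a preset correlation of 0.01. All list members were named entries, so the remaining entries they were set against were mainly the 393 novel_miR ones. The other 3 lists, for copper and laccase, NBS-LRR resistance genes and MYB transcription factors, had 0 families in the table.

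Named entries followed a rule fixed before the data were examined. For each comparison it took, among entries past the threshold with non-overlapping groups and a mean of at least 10 CPM in 1 group, up to 8 rises and 8 falls among named entries and up to 4 of each among novel_miR entries. Non-overlap was not asked for in the difference of effects. Where fewer than 6 entries passed, the 6 with the smallest p were named as not past the threshold. Families past the threshold were named up to 12, together with the 3 most abundant families of each list. Where the text names an entry outside this rule it says so.

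Alternatives fixed beforehand were pseudocounts of 0.1 and 10, no filter, a mean of at least 10 CPM, median-ratio scaling, a fit to the compared groups only, the replicate number as a block, each sample left out in turn, edgeR 4.0.16 quasi-likelihood tests on the recovered reads, a minimum log2 fold change of 1, camera with an estimated correlation, and fry. Alternatives chosen after seeing the data were 1 entry per distinct profile, leaving out the replicate 2 libraries of both inoculated groups, recovered reads as a covariate, DESeq2 1.42.0 on the recovered reads, and, for the difference of effects, a replicate block shared by leaf and fruit. The last was added because inoculated leaf and fruit samples of the same number had correlated deviations from their group means (0.76, 0.88 and 0.50 for numbers 1, 2 and 3), each the highest with its own number. This pairing comes from the data alone, as the labels state no shared plant, batch or day. The deviations of a group cancel out, so the 3 correlations are not independent. A deviation shared by the number 2 samples can raise those of numbers 1 and 3.

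The tests were checked on simulated data, in 10 simulations with 200 entries changed per comparison and between 514 and 517 entries tested. For the leaf comparison limma recovered 20.4% of 2-fold, 56.7% of 4-fold and 84.8% of 8-fold changes, and for the fruit comparison 20.9%, 53.1% and 76.8%. Of the simulated calls 19.4% in leaf and 24.6% in fruit were false. With median-ratio scaling these shares were 2.46% and 4.27%, and with edgeR 3.18% and 1.97%. The 2 limma fits used the same simulated values and differed only in the scaling, so the scaling made the gap between them. The CPM scale passes changes of abundant entries on to the others, but whether the gap arose in that way was not tested. A 4-fold change of the miR395 family was called in 10 of 10 simulations in either tissue, beside 3 calls of unchanged families in leaf and 4 in fruit over those simulations. Simulated entries were drawn independently, also those with identical values in the real table, and without deviations shared between entries. The family result is therefore too favourable, and the shares above need not hold for the real libraries. With 200 entries changed, the adjusted threshold is also easier to pass than where few entries change. The real tests called 9 entries in leaf and 0 in fruit, so the recovered shares may be too high for such a setting. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.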

Results

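Small RNA was profiled in leaves and fruits of lychee 24 h after inoculation with Peronophythora litchii or after a water mock, with 3 libraries in each of the 4 groups. Recovered depth was 804191, 1521425 and 1033375 reads in inoculated leaf, 752829, 609280 and 867881 in mock leaf, 354201, 417466 and 282775 in inoculated fruit, and 366285, 337121 and 392460 in mock fruit. With each distinct profile counted once, named miRNAs took 33.5% to 41.6% of the reads in leaf and 21.1% to 26.1% in fruit. The most abundant family, miR159, which targets GAMYB transcription factors, accounted for a summed 463990 ± 17283 CPM (SD, n = 3) in mock leaf and 349159 ± 2321 CPM in mock fruit. This sum counts the reads of the identical hbr-miR159a, mes-miR159b and rco-miR159 3 times. A single one of these entries held 14.9% to 16.1% of the CPM in mock leaf and 11.6% to 11.7% in mock fruit.

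Tissue was the largest difference between libraries, and the first principal component held 66.1% of the variance and separated leaf from fruit. The second held 25.0% and set the replicate 2 library of each inoculated group apart. Inoculated leaf replicate 2 correlated with the other leaf libraries at 0.789 to 0.931, whereas those libraries correlated with each other at 0.936 to 0.989. For inoculated fruit replicate 2 the range was 0.834 to 0.881, against 0.961 to 0.984. The median novel_miR entry stood at 40.8 CPM in inoculated leaf replicate 2, against 85.2 and 64.4 CPM in the other inoculated leaves and 93.9 to 132 CPM in mock leaves. It stood at 45.5 CPM in inoculated fruit replicate 2, against 147 and 173 CPM in the other inoculated fruits and 130.0 to 147 CPM in mock fruits.

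**Figure D1:**
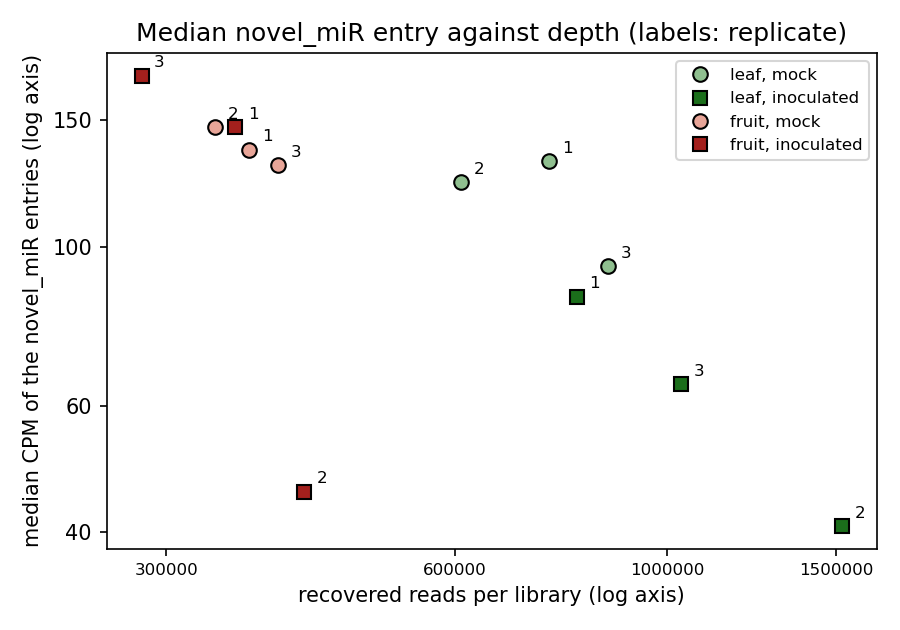
Median CPM of the distinct novel_miR entries in each of the 12 libraries (vertical, log axis) against recovered reads (horizontal, log axis), with the replicate number beside each point. The replicate 2 libraries of both inoculated groups have the lowest medians of their tissues, 40.8 CPM in leaf and 45.5 CPM in fruit. The vertical values are scaled by the totals on the horizontal axis, so the 2 axes are not independent.

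The first comparison asked which miRNAs differed in leaves 24 h after inoculation. The miR395 family, which targets ATP sulfurylases and a sulphate transporter, was 7.16-fold higher in inoculated leaves. Its summed level was 6836 ± 1807 CPM (SD, n = 3) in inoculated leaf and 941 ± 145 CPM in mock leaf, a log2 fold change of 2.84 (SE 0.30, limma adjusted p = 6.61e-06). The mature miR395b-3p stood behind this sum. It is listed 7 times with identical values, as csi-miR395b-3p, vvi-miR395b, vvi-miR395c, vvi-miR395e, vvi-miR395h, vvi-miR395k and vvi-miR395m. It reached 838, 1272 and 815 CPM in the 3 inoculated leaves and 134, 113 and 154 CPM in the mock leaves (log2 fold change 2.83, SE 0.30, limma adjusted p = 7.08e-05), on 674 to 1935 reads per inoculated and 69 to 134 reads per mock library.

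**Figure D2:**
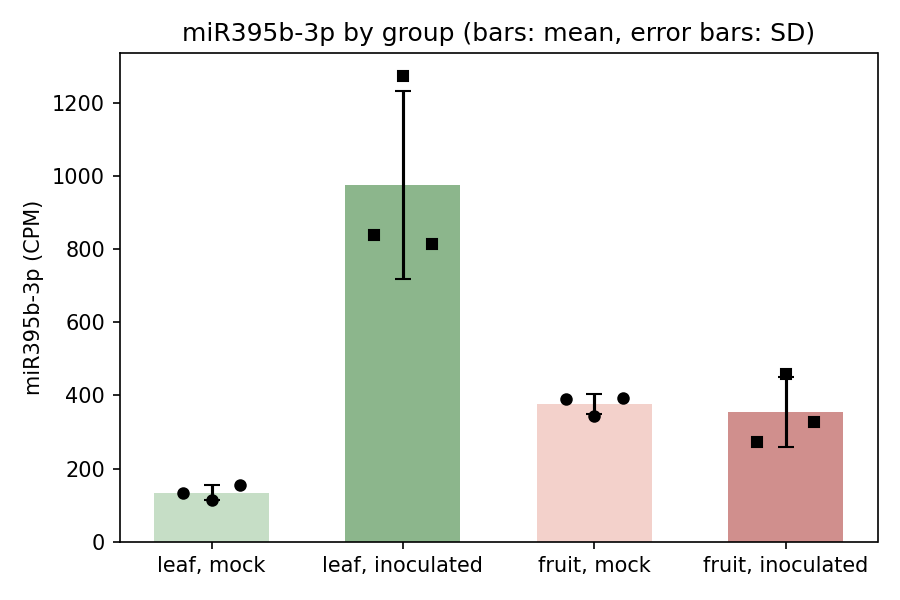
CPM of miR395b-3p in each library (points), with the mean (bars) and SD (error bars) of each group of 3. The 3 inoculated leaves lie between 815 and 1272 CPM and the 3 mock leaves between 113 and 154 CPM, while the fruit groups overlap.

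Of the 517 entries tested in leaf, 9 passed the threshold (8 higher, 1 lower), which were 3 distinct profiles, and 96 had an unadjusted p under 0.05. Besides miR395b-3p, novel_miR_143 was higher in inoculated leaves (5012 ± 420 against 1755 ± 331 CPM, SD, n = 3, log2 fold change 1.53, SE 0.30, limma adjusted p = 0.0182). The entry novel_miR_34 was lower (11531 ± 1410 against 31778 ± 3588 CPM, log2 fold change -1.46, SE 0.30, limma adjusted p = 0.0242). These 2 calls were lost under most alternatives. The first passed in 8 of 18 and the second in 6 of 18, with log2 fold changes from 1.21 to 2.35 and from -1.56 to -0.74. Median-ratio scaling moved the median log2 fold change of all entries in leaf by 0.58, from -0.34 to 0.24, and with it 7 entries were higher and 0 lower. Relative to that shift novel_miR_34 had a log2 fold change of -0.74 (limma adjusted p = 0.194). The shift was 0.12 in fruit, -0.44 for the difference of effects and -0.12 for the tissues. Without both inoculated replicate 2 libraries 36 entries passed (11 higher, 25 lower), and DESeq2 called 22 (16 higher, 6 lower). Without only that of leaf 7 passed (7 higher, 0 lower), so the 36 depended on leaving out a fruit library too, through the shared estimate of the spread.

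Among the fixed lists in leaf, the nutrient supply list held 12 tested entries of miR395, miR399 (which targets PHO2) and miR2111 (which targets F-box genes). All 7 members that rose were the identical miR395b-3p entries, and 7 also rose when adjusted over the list alone. The miR2111 family was at 8.41 ± 5.57 CPM in inoculated and 9.66 ± 6.08 CPM in mock leaf, and miR399 at 1.27 ± 1.24 and 1.98 ± 1.74 CPM (SD, n = 3). In the other lists no member passed, over all entries or adjusted over the list alone. Their most abundant families were, in inoculated and mock leaf, miR156 (SPL transcription factors, 516 ± 136 and 241 ± 22.1 CPM), miR157 (9.48 ± 1.48 and 4.56 ± 0.979 CPM, a profile also listed under miR156 names), miR167 and miR160 (auxin response factors, 12209 ± 4875 and 9140 ± 702 CPM, and 459 ± 317 and 227 ± 66.4 CPM), miR166 (HD-ZIP III factors, 91540 ± 44630 and 57806 ± 4573 CPM), miR164 (NAC factors, 1224 ± 844 and 475 ± 86.7 CPM), miR159 (466840 ± 61346 and 463990 ± 17283 CPM) and miR162 (DCL1, 41527 ± 5862 and 31847 ± 4173 CPM).

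Tested as sets against the remaining entries with camera at its preset correlation, all 5 lists in leaf ranked higher. The remaining entries were mainly novel_miR ones, whose median was 40.8 to 85.2 CPM in inoculated and 93.9 to 132 CPM in mock leaf. The 5 tests were therefore not independent. By themselves they could not tell a rise of a target class from lower novel_miR entries. Identical entries counted as separate members. The adjusted p was 2.74e-11 for nutrient supply, 3.96e-11 for phase change, 3.45e-05 for auxin signalling, 3.45e-05 for growth transcription factors and 0.0203 for RNA silencing machinery. With all libraries none of these calls held with an estimated correlation, where adjusted p = 0.0777 for nutrient supply, 0.206 for phase change and 0.329 for the other 3. With recovered reads as a covariate 1 list passed. The inoculated leaf replicate 2 library, which stood apart, had the highest level of the 6 leaf libraries in miR156, miR160, miR162, miR164, miR166, miR167, miR171 and miR319, for example 2166 CPM of miR164 against at most 970 CPM in the others. It was also highest in miR395, at 8921 CPM against 5873 and 5714 CPM in the other inoculated leaves. Without both inoculated replicate 2 libraries 4 lists passed at the preset correlation. With an estimated one only nutrient supply then passed (adjusted p = 0.0321), with 0.248 for phase change and 0.403 for the other 3.

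The same comparison in fruit gave 0 of 517 entries and 0 of 14 families past the threshold with limma, with 25 entries at an unadjusted p under 0.05 and a smallest adjusted p of 0.274. The count tests on recovered reads, edgeR and DESeq2, also gave 0. The 6 entries with the smallest p were all numbered novel_miR, and none of the 6 passed (limma adjusted p = 0.274 for each). Inoculated and mock fruit (mean ± SD, n = 3) stood at 382 ± 102 and 1024 ± 177 CPM for novel_miR_49, 92.8 ± 41.0 and 23.3 ± 10.0 CPM for novel_miR_89, 1222 ± 124 and 678 ± 144 CPM for novel_miR_91, 6.91 ± 6.47 and 25.7 ± 3.91 CPM for novel_miR_357, 3248 ± 1085 and 1574 ± 118 CPM for novel_miR_41, and 85.9 ± 43.9 and 23.9 ± 5.30 CPM for novel_miR_305. The miR395 family stood at 2508 ± 692 CPM in inoculated and 2641 ± 189 CPM in mock fruit. Leaving out inoculated fruit replicate 2 gave 6 calls, leaving out inoculated fruit replicate 3 gave 8, and leaving out both inoculated replicate 2 libraries gave 10.

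No member of any list passed in fruit, whether over all entries or adjusted over the list alone. As sets, the auxin signalling list (camera adjusted p = 7.23e-06) and the phase change list (0.0390) ranked higher than the remaining entries in inoculated fruit. With an estimated correlation the adjusted p was 0.964 for both. Both rested on inoculated fruit replicate 2, in which miR156 stood at 12981 CPM against 4558 to 6026 CPM in the other fruits and miR167 at 5866 CPM against 2228 to 2956 CPM. Without that library 4 lists passed and all 4 ranked lower, phase change among them (camera adjusted p = 0.00300, and 0.485 with an estimated correlation).

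Whether inoculation acted differently in the 2 tissues was tested as the difference of the 2 effects. Only miR395b-3p passed, with its 7 identical entries, out of 31 entries at an unadjusted p under 0.05. Its level in fruit was 274, 460 and 329 CPM after inoculation and 390, 344 and 392 CPM after mock. The effect in fruit was below that in leaf by a log2 difference of -2.95 (SE 0.43, limma adjusted p = 0.00151), and for the summed family by -2.95 (SE 0.42, adjusted p = 1.75e-04). The call was lost with median-ratio scaling (log2 difference -3.45, limma adjusted p = 0.0747), with edgeR (-2.88, adjusted p = 0.0939) and with the replicate number as a block (-2.95, limma adjusted p = 0.0586). It held with DESeq2 (-3.30, adjusted p = 0.00801). Inoculated leaf and fruit samples of the same number deviated together, and with a replicate block shared by them 58 entries passed (40 higher, 18 lower), miR395b-3p among them (-2.95, limma adjusted p = 7.41e-06). This block was chosen from the same data, so its p-values may be too small. Without both inoculated replicate 2 libraries 48 entries passed, 38 higher and 10 lower, where the main test had 0 higher and 7 lower.

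The mock libraries of fruit and leaf were compared as the tissue background. The miR156 family was 21.9-fold higher in fruit (5321 ± 619 against 241 ± 22.1 CPM, SD, n = 3), a log2 fold change of 4.45 (SE 0.39, limma adjusted p = 8.08e-07). This sum counts reads more than once, as its 46 listed entries were 13 distinct profiles. Several of these profiles had nearly the same reads in mock fruit, 519 to 523 each. The level and the fold change therefore depend on how many names shared reads. With 1 entry per distinct profile the log2 fold change was 4.84 (limma adjusted p = 4.09e-07), with near-identical profiles still counted separately. The families miR171, which targets HAM/SCL factors, miR319, which targets TCP factors, and miR167 were 18.0-fold, 7.29-fold and 3.74-fold lower in fruit. These 4 calls also held with median-ratio scaling, edgeR and DESeq2. In all, 11 of 14 families passed, 3 higher in fruit (miR156, miR162 and miR395) and 8 lower (miR157, miR159, miR160, miR166, miR167, miR171, miR319 and miR2111). With edgeR 1 family was higher and 5 were lower, and with median-ratio scaling or DESeq2 1 was higher and 4 were lower. The calls of miR157 and miR2111 each rested on 1 read in mock fruit, which for miR2111 was counted under 2 identical names. The calls of miR162 (1.85-fold), miR395 (2.82-fold), miR159 and miR2111 were lost with all 3 alternatives at similar log2 fold changes, of 0.72 to 0.78 (main test 0.89) for miR162, 1.32 to 1.38 for miR395, -0.56 to -0.52 (main test -0.41) for miR159 and -2.47 to -2.28 (main test -2.39) for miR2111. The direction of each called family was the same as in the main test.

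**Figure D3:**
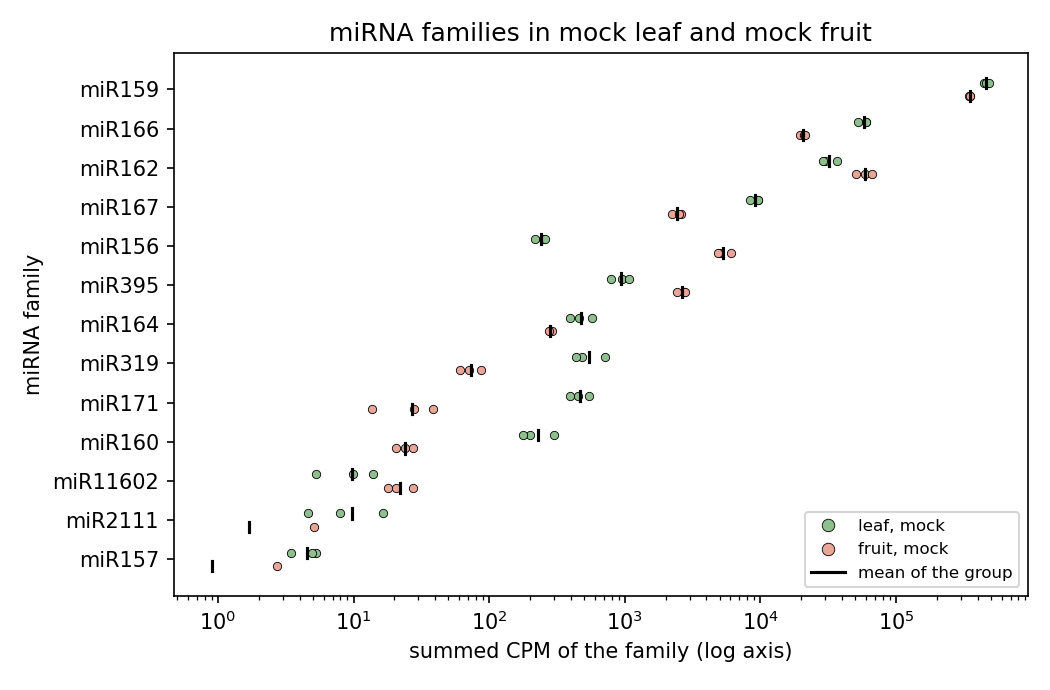
Summed CPM of each miRNA family (horizontal, log axis) in the 3 mock leaf and 3 mock fruit libraries (points; libraries at 0 are not drawn) with the group mean (line, zeros included). On these sums, which count a read once for each entry that lists it, miR156 lies higher in fruit by 21.9-fold and miR171 lower by 18.0-fold. The family miR399, at 0 in mock fruit, is not shown.

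Single entries differed too, but not all in the direction of their family. Of 46 miR156 and miR157 entries 15 were higher and 26 lower in fruit. The miR156 entries named below had 519 to 523 reads each over the mock fruit libraries. They may be largely the same reads, and so are no separate support for the family sum. Of 517 entries, 259 differed between mock fruit and mock leaf (115 higher in fruit, 144 lower, limma), which were 85 distinct profiles higher and 84 lower. The identical mdm-miR156u and mdm-miR156v stood at 471 ± 55.8 CPM in mock fruit (SD, n = 3) and at 0 in mock leaf. This is at least 352-fold higher, taking the floor of 3 reads over the group. The entries gma-miR156h, gma-miR156k, gma-miR156n, gma-miR156o, mes-miR156e and mes-miR156f each stood at 475 ± 57.1 CPM in mock fruit and 7.48 ± 1.51 CPM in mock leaf. Lower in fruit were mdm-miR171f-5p (72.1 ± 29.8 CPM in leaf and 0 in fruit, at least 25.4-fold) and the identical fve-miR160b, mdm-miR160c and mdm-miR160e (11.4 ± 3.27 CPM and 0, at least 4.10-fold). The identical csi-miR171a, mdm-miR171f-3p, rco-miR171a and rco-miR171b were 22.6-fold lower in fruit (95% exact interval 6.08 to 189, from 92 reads in leaf and 2 in fruit).

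Among novel_miR entries, the identical novel_miR_17 and novel_miR_236 were 124-fold higher in fruit (8452 ± 736 against 67.4 ± 7.25 CPM, SD, n = 3, limma adjusted p = 3.99e-10). The entry novel_miR_320 was 189-fold higher (1133 ± 101 against 5.29 ± 2.42 CPM), and novel_miR_249 was 145-fold higher (95% exact interval 49.0 to 709, from 214 reads in fruit and 3 in leaf). Higher in leaf were novel_miR_74 (58.9-fold, 2342 ± 334 against 40.3 ± 15.9 CPM), novel_miR_89 (36.0-fold, 834 ± 184 against 23.3 ± 10.0 CPM) and the identical novel_miR_36 and novel_miR_88 (37.1 ± 6.96 CPM in leaf and 0 in fruit, at least 13.6-fold). Across fixed lists, 34 of 36 tested entries of the growth transcription factor list and 18 of 23 of the auxin signalling list were lower in fruit, and 35 and 22 when adjusted over the list alone. Over all entries these were 16 of 18 and 6 of 10 distinct profiles. These 2 lists ranked lower with camera (adjusted p = 1.13e-11 and 5.41e-07) but not with an estimated correlation (adjusted p = 0.278 and 0.509). Of 46 phase change entries, 15 were higher and 26 lower in fruit, before and after adjustment over the list alone, but most of the lower entries were identical sets: of 12 distinct profiles 6 were higher and 3 lower. The RNA silencing list had 5 of 6 and the nutrient supply list 7 of 12 entries higher in fruit, with the same counts adjusted over the list alone (camera adjusted p = 0.0552 for both). The 7 were the identical miR395b-3p entries, 1 of 4 distinct profiles.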

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

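The tests on sequencing depth, on the deviating libraries, on the miR395b hairpin and on mixed tissue, and the 28 splits that kept inoculated pairs together, were chosen after the results were seen. The other counts of sample splits were planned.

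The response of miR395 to inoculation differed between the tissues by the test of the difference itself, though not under every alternative. The log2 effect in fruit minus that in leaf was -2.95 for csi-miR395b-3p and its identical entries vvi-miR395b, vvi-miR395c, vvi-miR395e, vvi-miR395h, vvi-miR395k and vvi-miR395m, and -2.95 for the miR395 family. The call of the entry was lost with the replicate block within tissue (limma adjusted p = 0.0586), with median-ratio scaling (0.0747) and with edgeR (adjusted p = 0.0939), and that of the family with the last 2 (0.0575 and 0.0978). The log2 differences in these fits were -2.95, -3.45 and -2.88 for the entry and -3.45 and -2.86 for the family. With each of the 12 samples left out in turn the entry passed, at -3.15 to -2.74 (limma adjusted p = 4.40e-04 to 0.00848), so no single sample carried the difference.

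Sequencing depth and a single deviating library were tested as technical origins of the miR395 rise in leaf. A batch that followed the treatment was not tested and cannot be told apart from it here. With recovered reads as a covariate the log2 fold change of miR395b-3p was 2.42 (SE 0.29, limma adjusted p = 2.33e-04), which argues against sequencing depth as the whole cause. Without inoculated leaf replicate 2 it was 2.63 (SE 0.31, adjusted p = 3.89e-04), so that library did not carry it. The other arm, csi-miR395b-5p, had a log2 fold change of 2.12 (SE 0.90) in the same direction, as higher output of the whole hairpin would give, but on 43 and 7 reads in all and with an adjusted p of 0.244. A response of leaf miR395 to the inoculation stays open as a hypothesis.

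The replicate 2 libraries of both inoculated groups stood apart along the same direction (Pearson r of 0.914 over 280 distinct entries that are not independent, 182 lower and 77 higher in both), and none of the explanations tested covered both tissues. Of the distinct novel_miR entries with at least 20 reads in both other inoculated libraries, 28% in leaf and 51.9% in fruit had under 1/2 of the lower of those 2 read counts. With replicate 1 or 3 in its place the share was 5.29% and 0% in leaf and 1.25% and 6.29% in fruit. This argues against a background that kept its reads while miRNA reads were added. Within a limited sequencing output a diluted background would also lose reads, so dilution of that kind was not excluded. The change of this library from mock correlated with that of inoculated replicates 1 and 3, across 394 entries that are not independent and over 3 splits of the mock libraries, at a median of 0.64 in leaf, as a stronger response would give, and at -0.27 in fruit, which argues against one there and, given the shared direction, leaves the reading of the leaf value open. Leaf RNA mixed into the fruit library was argued against as the whole cause: the best-fitting leaf share was 19.5%, while the 7 leaf-dominated entries changed by a median of 5.0% of their leaf level, from -3.80% (novel_miR_34) to 20.3% (novel_miR_308); what set these libraries apart stays open, and no record of a shared batch was in the labels.

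Other splits of the same samples were counted for each test across all entries. With 3 samples against 3 there are 10 splits, too few for a share under 0.05. In leaf the real split gave 9 miRNAs and the highest other split 0, with 1 family against 1 (2 of 10 splits gave as many) and 5 lists against 5 (5 of 10). In fruit it gave 0 miRNAs against 0 and 0 families against 0 (10 of 10 for each), and 2 lists against 5 (10 of 10). For mock fruit against mock leaf it gave 259 miRNAs against 0 and 11 families against 0. For the difference of effects, 12 of 100 drawn splits gave at least the real 7 miRNAs (highest other 14) and 12 gave at least the real 1 family (highest other 2), so chance was not excluded by this count. That draw did not keep inoculated leaf and fruit samples of the same number together. The 28 splits that did could not test the difference apart from the leaf effect either, since all 27 others regrouped the leaf samples. All 12 splits of the 100 that gave as many miRNAs kept the real leaf groups and regrouped fruit samples or were the real split. No other drawn split kept the leaf groups, and none of the 88 that regrouped the leaf samples gave as many. The miRNA count therefore followed how many draws kept the leaf groups.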

How the results depend on the processing

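The distinct-profile, left-out replicate 2, covariate and DESeq2 alternatives, the replicate blocks shared by leaf and fruit, and the family tests for the difference of effects and the tissue comparison, were chosen after the data were seen. The 3p arm of miR395b in leaf passed in 18 of 18 alternatives, with log2 fold changes from 2.42 to 3.70, and the summed family did too. Of 1774 values of single entries and families under the alternatives, 1666 kept their side of the threshold, 89 lost it and 19 gained it. Where the main test or the alternative passed, 0 changed direction. Among values that passed in neither, direction was not counted and could change. The miR156 family went from -0.68 to 0.04 for the difference of effects with recovered reads as a covariate. Depth limits low entries: 1 read was worth up to 3.54 CPM in fruit. The causes of the changes below were not tested, except where fewer entries, samples or another scale were part of the alternative.

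With 1 entry per distinct profile, calls went from 9 to 1 in leaf, from 7 to 1 for the difference of effects and from 259 to 158 for the tissues, and fruit lists from 2 to 1. Without both inoculated replicate 2 libraries, calls were 36 miRNAs and 3 families in leaf, 10 miRNAs in fruit, 48 miRNAs and 2 families for the difference, and 4 fruit lists, all ranked lower where the 2 had ranked higher (adjusted p = 0.432 for all 4 with an estimated correlation). DESeq2 gave 22 miRNAs in leaf and 5 tissue families. Median-ratio scaling gave 0 miRNAs and 0 families for the difference, 1 fruit list and 5 tissue families, and edgeR 0, 0 and, for tissue families, 6. The covariate left 1 leaf list, a pseudocount of 0.1 left 1 fruit list, an estimated correlation 0 in leaf and 0 in fruit, and fry 1 and 0. The median-ratio and edgeR zeros stand beside 31 entries at an unadjusted p under 0.05 in limma and 10 calls by DESeq2.

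With each sample left out in turn, calls ranged from 7 to 8 miRNAs in leaf, 0 to 8 in fruit (6 without inoculated fruit replicate 2, 8 without replicate 3), 7 to 13 for the difference (13 without inoculated fruit replicate 2) and 203 to 234 for the tissues. Families were 1 to 1 in leaf, 0 to 0 in fruit, 1 to 1 for the difference and 7 to 9 for the tissues (7 without mock leaf replicate 1 or 2 or mock fruit replicate 2). Lists were 4 to 5 in leaf and 1 to 4 in fruit (4 without inoculated fruit replicate 2, 1 without mock fruit replicate 2 or 3).

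The replicate numbers did not pair inoculated with mock samples, nor mock leaf with mock fruit. Same-numbered inoculated and mock samples had correlated deviations of 0.35, -0.49 and -0.41 in leaf and -0.07, -0.22 and -0.03 in fruit, and mock leaf and fruit of -0.15, 0.08 and 0.01, and not every sample correlated best with its own number. The replicate block gave 7 miRNAs and 2 families in leaf, 0 miRNAs and 1 list in fruit, 0 miRNAs and 1 family for the difference and 263 miRNAs for the tissues, where the block was the plain number. Inoculated leaf and fruit samples of the same number deviated together, a pairing read from these data and not from the labels. For the difference a replicate block shared by them gave 58 miRNAs and 3 families, and one shared within each treatment 51 and 2. The call of miR395 held with both, and miR162 passed with both (log2 difference -0.54).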

Other observations

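The tests in this part were chosen after the data were seen, and so were the entries named from them. With the replicate 2 libraries of both inoculated groups left out, the leaf comparison rested on 2 inoculated and 3 mock libraries. The families miR156 (log2 fold change 0.86, SE 0.20, limma adjusted p = 0.00697) and miR11602 (1.60, SE 0.48, adjusted p = 0.0295) then passed beside miR395. The miR11602 family was 1 entry, and the left-out inoculated leaf replicate 2 stood at 12.5 CPM, within the 5.31 to 13.8 CPM of the mock leaves. In the same fit 25 entries were lower, some of them identical, among them the identical novel_miR_121, novel_miR_48 and novel_miR_65 at -1.57 (SE 0.26, limma adjusted p = 0.00322). With only inoculated leaf replicate 2 left out, miR156 had the same 0.86 at a limma adjusted p of 0.278. In that fit 1 family passed, and 7 entries were higher and 0 lower. Leaving out the fruit library too changed only the spread estimate that the leaf test shares with fruit. In fruit 10 entries passed, with novel_miR_357 lower (-2.67, SE 0.32, adjusted p = 0.00166, on 1 read in each remaining inoculated library and 8 to 10 per mock library) and novel_miR_196 higher (2.44, SE 0.51, adjusted p = 0.0315). The fruit call of vvi-miR156b (-1.90) rested on 0 reads in both remaining inoculated libraries and 1 read in each mock library.

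The 2 inoculated replicate 2 libraries deviated from the other inoculated libraries of their tissue along the same direction. Across 280 distinct entries with a mean of at least 50 CPM, which are not independent, the deviations in leaf and fruit had a Pearson r of 0.914 and a Spearman rho of 0.928. Of these entries 182 were lower and 77 higher in both tissues. Among the 15 named entries, 14 were higher in both, with miR164 (gma-miR164a) at log2 1.59 in leaf and 2.02 in fruit and miR166 (mes-miR166e) at 1.09 and 1.22, while miR159 (hbr-miR159a) was lower at -0.33 and -0.53.

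The fold changes of leaf and fruit across 391 distinct entries followed these libraries. With all libraries the Pearson r between the inoculation effects in leaf and fruit was 0.457 and 69.6% of entries had the same sign. Without the replicate 2 libraries r was -0.153 and 35.3% had the same sign. The groups compared in leaf and in fruit shared no libraries.

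The median novel_miR entry fell with depth within each tissue, on log2 scales over 6 libraries each and as 2 relations. CPM is reads divided by the same recovered total, so a fall is built in where these reads do not follow that total. In reads the median stood at 68.5, 62 and 66.5 in inoculated leaf and 99, 75 and 81.5 in mock leaf. In fruit it stood at 52, 19 and 49 after inoculation and 50, 49.5 and 51 after mock. The permutation p-values below take no account of the shared total, so they are no evidence of a relation beyond it. In leaf Pearson's r was -0.951 (exact permutation p = 0.00694, adjusted 0.0139) and Spearman's rho -0.886 (exact permutation p = 0.0333, adjusted 0.0333), with r of -0.893 after leaving out the 2 libraries farthest from the median depth. In fruit r was -0.729 (exact permutation p = 0.160, adjusted 0.160) and rho -1 (exact permutation p = 0.00278, adjusted 0.00556), with r of -0.940 without the 2 farthest. Inoculated leaf libraries included the 2 deepest, so depth and inoculation overlapped there. All pairs of replicates differed by more than sampling noise, with a chi-square per degree of freedom between 4.24 and 275.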
